A study of Homo sapiens with 4 samples.

How the data were processed

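MicroRNA (miRNA) abundance was compared between untreated SKBr3 cells, an established human breast cancer line, and SKBr3 cells treated with LAQ-824, a hydroxamate inhibitor of histone deacetylases. Per the labels, the dose was 20 µM and the treatment lasted 5 h. Per the labels' protocols, small RNA was isolated with a column kit, labelled by reverse transcription, and hybridised on 4 two-colour arrays, with untreated RNA in Cy3 and treated RNA in Cy5. The labels name no dye swap, so dye and treatment ran together on each array. The labels call the arrays replicates and do not say whether they came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

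The authors' deposited value table holds one log2 ratio per spot and array, built on ratios of median spot intensity from GenePix 3.0, per the labels. The table names neither its scale nor its direction. It was read as log2 of treated over untreated because the dyes in the labels run that way, because the miRNA means rank as on a sheet of the authors' workbook whose positive values are called increased, and because the workbook's protocol equates log values with powers of 2. Normalization of the value table is not given in the sources used here. Its array medians over the tested miRNAs lie at -1.78, -3.03, -1.38 and -2.80, so it is not centred. The deposited workbook also holds the log2 ratios the authors entered into SAM (significance analysis of microarrays), 1 value per miRNA and array. Their means across arrays lie 1.41 above those of the value table (median over 49 miRNAs with a value on all 4 arrays of both; 5th to 95th percentile 1.38 to 1.56), and 44 of the 49 lie within 0.1 of that difference. How the authors made this shift is not given in the sources used here. The columns of that sheet name the comparison but no replicate, so they were used as 4 unnumbered arrays. Across miRNAs each column correlated best with a different array of the value table, at r of at least 0.94. This match was not used. A further 8 columns of array values on the sheets of significant miRNAs were not used. The authors' deposited SAM output gives a score per miRNA and a q-value in percent for a one-class test with 24 permutations, row-average filling of missing values and at most 1 missing array, per the file headers. A level sheet gives the authors' mean background-subtracted Cy3 intensity of untreated cells for 67 miRNAs, from 177 to 22737 with a median of 1915, and a scaled score of it that the authors' header calls 0.0002 times the mean, while its values are 0.0005 times the mean. The authors' means carry no error. They were set against the log2 ratios across probes in tests of a trend with brightness, where differences between probes in labelling and binding enter too.

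Of the rows of the value table, 378 are probes for 189 miRNA names with 2 spots each, 360 are buffer spots and 30 are probes marked rev. A ratio was given for 122 of the miRNA probes, for 1 buffer spot and for 0 of the rev probes. No control RNA with a ratio was identified among the rows. The 2 spots of a miRNA were averaged per array, and where 1 spot had a ratio that value was used. Of 61 miRNAs with a ratio, the 59 with a value on at least 3 of 4 arrays were tested, and 53 of these had a value on all 4. Pearson's r between the 2 spots across miRNAs was 0.825 to 0.841 per array, and the median absolute difference was 0.26 to 0.31 log2. The number of arrays limits the precision. All 59 names were matched to RefSeq genes of the GRCh38.p14 table, used here for names and for which miRNA genes lie within 10000 bases of each other. Members of one family differ by few bases and may hybridise to each other's probes; values of such members are uncertain in that respect.

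The mean log2 ratio of each miRNA was tested against 0 with limma 3.58.1 (R 4.3.3; lmFit with an intercept, eBayes), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. On the value table and on the SAM sheet eBayes estimated infinite prior degrees of freedom, so each miRNA was tested with one pooled SD (1.07 and 0.924 log2) taken as known. The resulting adjusted p-values can be far smaller than 4 arrays alone would give, and counts from the ordinary one-sample statistic, which uses each miRNA's own spread, are therefore printed beside them. SDs given with means are each miRNA's own SD across arrays. The array-wide direction was tested on the 4 array medians by an exact two-sided sign-flip permutation test. Fixed lists with at least 3 tested members were tested with fry (one-way), after filling missing values with the row mean, and with camera as an alternative. The lists were drawn up from textbook families, clusters and tissue-restricted miRNAs. Each count is also given for values centred on each array's median and for the authors' SAM sheet, because these scales move the split between higher and lower calls.

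Named miRNAs were the 15 largest mean decreases and up to 10 largest mean increases among miRNAs past the threshold with one sign on every array, up to 4 members of each fixed list by absolute mean log2 ratio, and miR-21, miR-27a, miR-27b, let-7a, miR-125b and miR-16. This gave 41 miRNAs. Other miRNAs that are named were chosen after their values were seen. The test, the lists, the naming rule and most alternatives were set before the data were examined. Alternatives were other scalings, filters, sources of the values, tests, thresholds and sets of arrays. The planned scaling of arrays to one spread was run as scaling to one median absolute log2 ratio, the form limma uses for ratios. The median of a miRNA's spots equals their mean with 2 spots and tests nothing.

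The procedure was tested on simulated data. With 59 miRNAs and the spread of the value table, 82.1% of miRNAs lowered by 2 log2 units and 28.1% of those lowered by 1 were recovered, with 2.53% false calls. With 52 miRNAs and the spread of the SAM sheet, the shares were 92.5% and 44.8%, with 2.39% false calls. With 59 miRNAs and the spread of the values centred on the array median, they were 90.5% and 61.9%, with 2.45% false calls. The simulated values were not themselves centred, so these last shares do not show what centring does to recovery or false calls. These simulations drew independent errors. In a simulation added after the data were seen, with no true change but a constant shared by all miRNAs of an array, the value table's test made at least 1 call in 17.1% of 1000 simulated tables, and the SAM sheet's in 20.3%. As many calls as in the real data appeared in 0% of these tables for the value table and in 0.9% for the SAM sheet. The constants varied between arrays with an SD of 0.793 log2 for the value table and 0.619 for the SAM sheet. The simulation held no offset common to all arrays, such as a difference between the dyes could give. These shares therefore do not tell whether such an offset alone could give as many calls. For the sign-flip SAM statistic, an initial test that asked for nearly all of 7 shifted rows in 1 simulated table was not met, and it was replaced by averages over 100 tables of 60 rows. These gave 82.9% recovery with 7 shifted rows and 95% with 20, with 6.87% and 5.17% false calls against a nominal 5%. Tables were prepared in Python 3.11.15 with pandas 2.3.3.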

Results

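Hybridisation of 4 two-colour arrays compared miRNAs of SKBr3 breast cancer cells treated with the histone deacetylase inhibitor LAQ-824 (20 µM, 5 h) with those of untreated cells. The comparison addresses whether miRNA levels differ after 5 h of inhibition of histone deacetylases, enzymes that remove acetyl groups from histones and other proteins. Each array carried both RNAs, and there was 1 group of 4 arrays. A ratio was given for 55 to 59 of the 59 tested miRNAs per array.

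Most measured miRNAs had a lower signal in treated than in untreated cells. Of 59 tested miRNAs, 53 fell and 0 rose on the deposited value table (limma, adjusted p under 0.05), and 0 had a higher mean at an unadjusted p under 0.05. The largest decreases were those of miR-141, let-7f, miR-27b and miR-19a. The log2 ratio of miR-141, a member of the miR-200 family that restrains epithelial-mesenchymal transition, was -5.74 ± 1.35 (SD, n = 3). The size of this value is uncertain, because its 2 spots were -7.33 and -4.89 on replicate 1 and -5.26 and -3.23 on replicate 3, and replicate 2 rests on 1 spot. Let-7f, of the let-7 family that represses RAS and other growth genes, fell by 4.95 ± 0.90 (SD, n = 4), which is 30.9-fold. MiR-21, an abundant miRNA in breast tumours, fell by 3.84 ± 0.72 (SD, n = 4), which is 14.3-fold.

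The size of this fall depends on the scale. The mean of the 4 array medians was -2.25 ± 0.79 (SD, n = 4), a 4.75-fold lower typical ratio. In an exact two-sided sign-flip permutation test on these medians p was 0.125, the smallest 4 arrays can give. On the authors' SAM sheet the same mean was -0.80 ± 0.62 (SD, n = 4), a shift of 1.45 in the medians between the deposited tables. On that sheet 17 of 52 miRNAs fell and 0 rose by limma (unadjusted p under 0.05 for 22, of which 1 was higher). Centring each array on its median places about as many miRNAs above 0 as below it by construction, so that scale ranks miRNAs within an array and says nothing of an array-wide fall. On it 9 of 59 miRNAs were lower and 8 were higher, and without replicate 1 there were 6 lower and 2 higher, with 5 higher without each of the other replicates. The ordinary one-sample statistic called 34 miRNAs lower on the value table, 0 on the SAM sheet, where 17 had an unadjusted p under 0.05, and 3 relative to the array median, of which 1 was higher. Without array values whose 2 spots differed by over 1 log2 unit, a filter chosen after the data were seen, 8 miRNAs had under 3 arrays left, namely miR-141, let-7d, miR-27b, miR-99b, miR-128a, miR-148a, miR-98 and miR-30a-3p, of which miR-98 and miR-30a-3p were named after their values were seen. With no dye swap, a difference between the dyes cannot be separated from the array-wide fall.

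**Figure D1:**
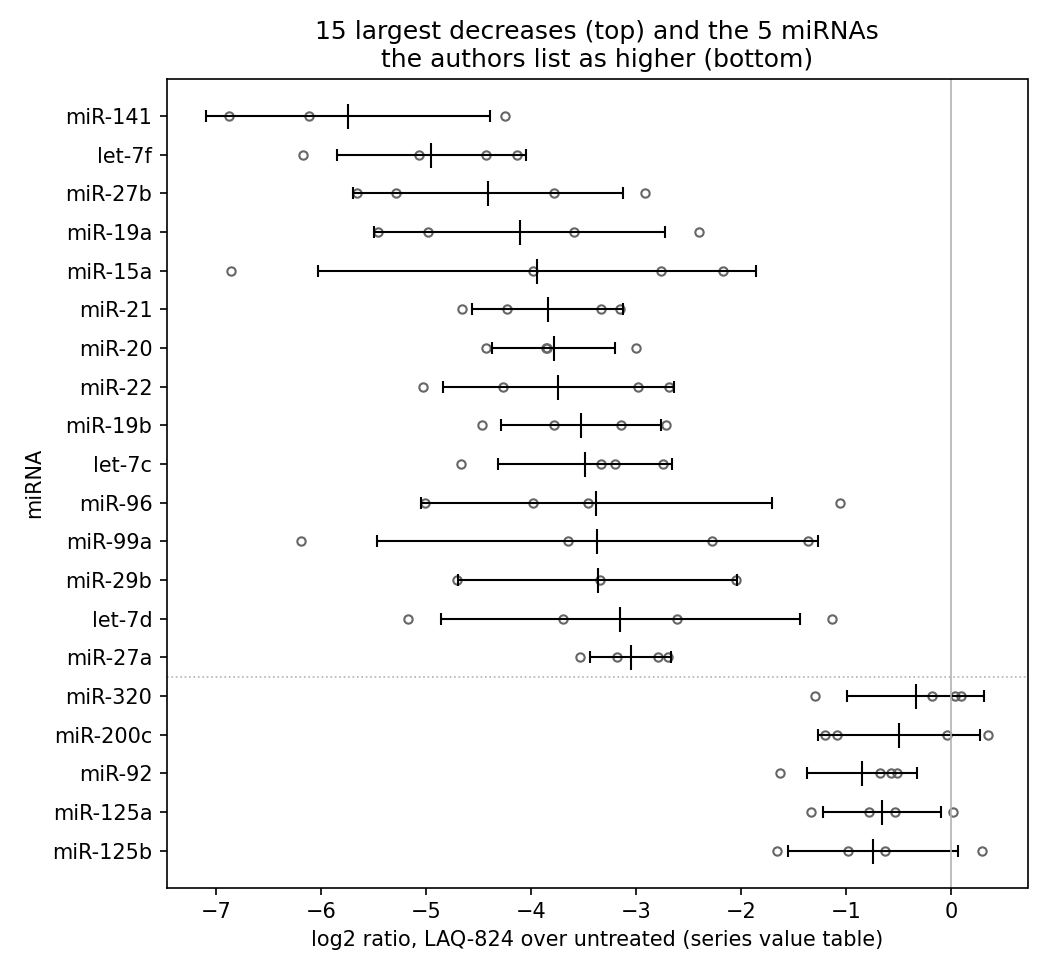
Log2 ratio of treated over untreated cells (horizontal axis, series value table) for the 15 miRNAs with the largest decreases and, under the dotted line, the 5 the authors list as higher. Open circles are arrays, the tick is the mean and the bar its SD; miR-141 averages -5.74 and miR-320 -0.34.

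Both relative to the array median and on the SAM sheet, 8 miRNAs were called lower: let-7c, let-7f, miR-19a, miR-19b, miR-20, miR-21, miR-22 and miR-27b. Let-7f was -3.53 ± 0.79 on the SAM sheet and -2.70 ± 0.92 relative to the median (SD, n = 4), so its fall was 11.6-fold and 6.51-fold on these scales. MiR-27b was -4.41 ± 1.29 on the value table, -2.83 ± 1.23 on the SAM sheet and -2.16 ± 0.55 relative to the median. For miR-21 the last 2 values were -2.44 ± 0.57 and -1.60 ± 0.14. MiR-22 was -3.74 ± 1.10, -2.11 ± 0.94 and -1.49 ± 1.003 on the 3 scales. The size of its fall is uncertain, because its 2 spots were -2.535 and -6.004 on replicate 1 of the value table. Other large decreases on the value table did not pass as below the array median. They were miR-15a at -3.94 ± 2.08, miR-96 at -3.38 ± 1.67, miR-99a at -3.37 ± 2.10, miR-29b at -3.36 ± 1.33 (n = 3), let-7d at -3.15 ± 1.71 and miR-27a at -3.05 ± 0.39. Relative to the median, miR-15a was -1.70 ± 1.58 and lower on 4 of 4 arrays (limma, adjusted p = 0.0708), and miR-29b was -1.30 ± 1.75 and lower on 3 of 3 (limma, adjusted p = 0.185), while let-7c passed at -1.24 ± 0.89, lower on 3 of 4 arrays (limma, adjusted p = 0.0485). All 3 values of miR-29b and 3 of the 4 of miR-96 rest on 1 spot, as do 2 of the 4 each of miR-15a and miR-99a, among them their lowest, -6.86 and -6.19 on replicate 4. Without replicate 4 the means of miR-15a and miR-99a were -2.97 and -2.43 on the value table. Relative to the array median, miR-96, miR-99a, let-7d and miR-27a were -1.13, -1.12, -0.90 and -0.80 with all arrays. MiR-27a had a small SD on the value table, and its ratio on the SAM sheet was -1.66 ± 0.41 with an adjusted p of 0.00237 (limma), lower on 4 of 4 arrays. Without limma's moderation, the smallest adjusted p on that sheet was 0.0519.

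All 7 tested members of the let-7 family fell on the value table, 6 on the SAM sheet and 2 relative to the array median, and the counts adjusted over the list alone were also 7, 6 and 2. Without 1 of the arrays of the SAM sheet, let-7d went from -1.62 to -1.01 and did not pass, nor did let-7e (limma, adjusted p = 0.119 and 0.0791), and miR-98 did not pass without any of 3 of the 4 arrays (adjusted p = 0.0854, 0.105 and 0.281); let-7e and miR-98 were named after their values were seen. The family mean was -3.11 on the value table (fry, adjusted p = 0.0102). Fry tests a list against 0, and 53 of all 59 tested miRNAs fell on the value table. All 7 tested lists passed there with all arrays, so neither a pass nor a count of falling members sets a list apart from the other miRNAs. Set against the other miRNAs with camera, the family did not pass (adjusted p = 0.449, and adjusted p = 0.924 with an estimated correlation). The mean was -1.65 on the SAM sheet (adjusted p = 0.0415) and -0.86 relative to the median (adjusted p = 0.0691). Let-7f was followed by let-7c at -3.49 ± 0.83, let-7d and let-7a at -2.93 ± 0.65 (SD, n = 4). Without replicate 4 the fry adjusted p was 0.0698, and none of the 7 tested lists passed on the value table. The lists of miR-17, of miR-15 and miR-16, and of miR-30 also did not pass without replicate 1 (0.0610, 0.0843 and 0.0843) or without replicate 2 (0.0818, 0.131 and 0.131).

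In the miR-17 cluster and its paralogs, an oncogenic group induced by MYC, 8 of 9 tested members fell on the value table, also when adjusted over the list alone. The leading ones were miR-19a at -4.11 ± 1.38, miR-20 at -3.78 ± 0.59, miR-19b at -3.53 ± 0.76 and miR-106b at -3.02 ± 1.28 (SD, n = 4). On the SAM sheet 4 fell, with either adjustment, of which miR-106b did not pass without 1 array (limma, adjusted p = 0.0672). Relative to the array median, miR-19a, miR-19b and miR-20 were lower and miR-92 was higher, and adjusted over the list alone 4 were lower and 2 higher. The group's mean was -2.38 (fry, adjusted p = 0.0160), -0.97 on the SAM sheet (adjusted p = 0.103) and -0.14 relative to the median (adjusted p = 0.0724), where the group's median was 0.45. Set against the other miRNAs with camera, adjusted p was 0.961, and adjusted p = 0.983 with an estimated correlation.

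All 5 tested members of the clusters of miR-23, miR-27 and miR-24 fell on the value table, with a mean of -2.69 (fry, adjusted p = 0.0102). Camera gave an adjusted p of 0.755 for these clusters, and adjusted p = 0.924 with an estimated correlation. On the SAM sheet the mean was -1.25 (adjusted p = 0.0415) with miR-27a and miR-27b past the threshold, and relative to the median it was -0.45 (adjusted p = 0.0691) with miR-27b alone. The counts adjusted over the list alone were the same, 5, 2 and 1. MiR-23b at -2.11 ± 0.53 and miR-24 at -1.95 ± 0.71 (SD, n = 4) fell on the value table and lay at 0.13 and 0.29 relative to the array median.

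The miR-29 family, whose targets include collagens and DNA methyltransferases, had a mean of -2.72 (fry, adjusted p = 0.0102), and all 3 members fell on the value table: miR-29b, miR-29c at -2.53 ± 0.99 and miR-29a at -2.26 ± 1.04. Camera gave this family an adjusted p of 0.755, and adjusted p = 0.924 with an estimated correlation. Of 2 members on the SAM sheet 1 fell, miR-29c at -1.12 ± 0.82 (SD, n = 4; limma, adjusted p = 0.0499), a call lost without any of 3 of the 4 arrays (adjusted p = 0.143, 0.186 and 0.217), and relative to the median 0 of 3 passed. All 3 members of the family of miR-15 and miR-16, which represses BCL2, also fell on the value table, with a mean of -2.64 (fry, adjusted p = 0.0331). Camera gave adjusted p = 0.758, and adjusted p = 0.924 with an estimated correlation. Neither of its 2 members on the SAM sheet passed, and 0 of 3 passed relative to the median. MiR-16 was -2.23 ± 0.84 and miR-15b -1.76 ± 1.32 (SD, n = 4), and miR-16 lay at 0.02 ± 0.08 relative to the array median. In the miR-30 family 4 of 5 members fell on the value table, with a mean of -1.88 (fry, adjusted p = 0.0331), including miR-30b at -2.77 ± 1.46, miR-30c at -2.35 ± 1.11, miR-30a-5p at -2.05 ± 1.27 and miR-30d at -1.70 ± 0.82. For this family too camera gave adjusted p = 0.755, and adjusted p = 0.924 with an estimated correlation. MiR-30b alone of the 5 members fell on the SAM sheet, at -1.34 ± 1.35 (SD, n = 4; limma, adjusted p = 0.0145), and it was -0.75 and did not pass without the array at -3.13 (adjusted p = 0.296). Relative to the median 0 were lower and 1 was higher. The counts adjusted over each list alone were the same on all 3 scales, except that relative to the median 0 members of the miR-30 family were then higher. Relative to the median the means of these 3 families were -0.53, -0.40 and 0.33, with fry adjusted p of 0.0691, 0.666 and 0.163, so none passed. MiR-30a-3p, named after its values were seen, was the list member that did not pass on the value table (-0.55 ± 0.58, n = 3). It was 1.51 ± 0.82 relative to the median (limma, adjusted p = 0.0377). It is the strand opposite miR-30a-5p from the same gene, MIR30A. The 4 falls are thus those of the other members, and the 1 higher value is its own. Its mean lies above those of the other 4 members on the value table and relative to the median, and so raises the list's means. The list's fry and camera results include miR-30a-3p too and were not computed without it. Its replicate 3 value averages spots of 1.68 and -1.53, and its other 2 arrays rest on 1 spot each, so the value is uncertain.

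Of the 4 tested members of the group of miR-125, miR-99, miR-100 and miR-10, 2 passed as lower on the value table by limma. MiR-99a and miR-99b, at -2.49 ± 1.95 (n = 3; adjusted p = 0.0616 without replicate 2), fell on the value table by limma, whereas miR-125a at -0.66 ± 0.56 and miR-125b at -0.74 ± 0.81 (SD, n = 4) did not pass (limma, adjusted p = 0.234 and 0.180). Relative to the array median miR-125a was 1.59 ± 0.79 and miR-125b 1.505 ± 0.91, both higher on 4 of 4 arrays and past the threshold (limma, adjusted p = 0.0173 and 0.0278). On that scale miR-99a was -1.12 and miR-99b 0.045, and neither passed (limma, adjusted p = 0.169 and 0.953). MiR-125a lay above miR-99b by 1.88 ± 1.81 (SD, n = 3), with adjusted p = 0.0139 by limma and unadjusted p = 0.214 by the ordinary statistic. Whether the miR-99 and miR-125 members differ is thus not settled. The group mean was -1.81 (fry, adjusted p = 0.0361), -0.17 on the SAM sheet (adjusted p = 0.692) and 0.50 relative to the median (adjusted p = 0.156). Camera gave an adjusted p of 0.755, and adjusted p = 0.924 with an estimated correlation, with the group 0.59 above the other miRNAs. Without replicate 2, 3 or 4 the fry adjusted p was 0.150, 0.103 and 0.0963. MiR-99a alone of the 3 members on the SAM sheet passed there, at -1.99 ± 2.73 (SD, n = 3; limma, adjusted p = 0.00152), a mean carried by 1 array at -5.11, without which it was -0.43 and did not pass (adjusted p = 0.620). Adjusted over the list alone, 2 members were lower on the value table, 1 on the SAM sheet and 0 relative to the median, where 2 were higher. In the miR-200 family, miR-200c was -0.49 ± 0.77 (SD, n = 4) and did not pass (limma, adjusted p = 0.371), beside the fall of miR-141. Its mean ranged from -0.78 to -0.26 without 1 array. Relative to the median, miR-141 was -3.68 ± 0.75 (n = 3) and miR-200c 1.75 ± 0.33 (n = 4), both past the threshold and in opposite directions. MiR-200c was the 1 member on the SAM sheet, at 0.90 ± 0.63, and did not pass (limma, adjusted p = 0.120). The counts adjusted over the list alone were the same.

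Lists with fewer members are given as values on the value table and relative to the median. MiR-26a was -2.50 ± 0.43 and -0.25 ± 0.95. MiR-34a, whose gene is activated by p53, was -1.77 ± 0.49 and 0.48 ± 0.95. MiR-181a and miR-181b were -1.14 ± 0.98 and -1.98 ± 1.06, against 1.11 ± 0.62 and 0.27 ± 0.38. MiR-103 and miR-107 were -1.26 ± 1.03 and -1.76 ± 1.25, against 0.99 ± 0.33 and 0.49 ± 0.51. MiR-148a was -2.30 ± 0.62 and -0.05 ± 0.35, and miR-130a was -1.58 ± 0.50 and 0.49 ± 1.003 (n = 3). These 8 passed the test as lower on the value table, while relative to the median miR-181a and miR-103 passed as higher. Of the 8, 0 passed on the SAM sheet, with limma's adjusted p from 0.0523 for miR-26a to 0.728 for miR-103 and miR-130a, and miR-181a and miR-103 lay above 0 there, at 0.28 and 0.19. The counts adjusted over each list alone were the same, except that miR-26a, the 1 tested member of its list, then passed as lower on the SAM sheet. The value-table call of miR-103 was lost without replicate 1, 2 or 4 (limma, adjusted p = 0.0551, 0.137 and 0.128). That of miR-181a was lost without replicate 2 or 4 and with array weights (0.0986, 0.290 and 0.0602), that of miR-107 without replicate 2 (0.0568) and that of miR-130a without replicate 1 (0.128).

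MiRNAs typical of other cell types were mostly without a ratio, as were most miRNAs on the array, where 61 of all 189 names had one. Of 39 miRNAs on the array from the lists for muscle, nervous system, blood, liver, stroma and embryonic stem cells, 2 had one, both from the neural list: miR-128a at -2.52 ± 0.85 (SD, n = 3) and miR-128b at -1.72 ± 0.74 (SD, n = 4). Both fell on the value table (limma, adjusted p = 0.000138 and 0.00211). Relative to the array median these were -0.12 and 0.53, and neither passed the test. MiR-128b, the 1 of them on the SAM sheet, was -0.81 ± 0.78 (limma, adjusted p = 0.162). The counts adjusted over the list alone were the same, 2, 0 and 0. MiR-221 and miR-222 had no ratio, and the placental list had 0 members on the array.

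The authors' deposited table lists 27 miRNAs as significant by SAM, 22 lower and 5 higher, with q-values of 1.69% to 2.35%. The false discovery rate in that deposited table is 2.35% as the median over permutations and 15.8% as an upper percentile. The 5 higher ones were miR-320, miR-200c, miR-92, miR-125a and miR-125b, of which miR-320 and miR-92 were named after their values were seen. On the SAM sheet limma called 15 of the 22 lower miRNAs and 0 of the 5 higher ones. MiR-320 was 1.06 ± 0.66 there (SD, n = 4; limma, adjusted p = 0.0625), above 0 on 4 of 4 arrays. On the value table it was -0.34 ± 0.65 (limma, adjusted p = 0.531), a mean carried by replicate 4 at -1.30, without which it was -0.015. Relative to the array median all 5 were higher by the test with all 4 arrays, with miR-320 at 1.91 ± 0.82 and miR-92 at 1.40 ± 0.78. On the value table all 22 of the authors' lower miRNAs fell, but so did 53 of all 59 tested miRNAs. Of the 5 higher ones, 0 passed there. Relative to the array median 8 of the 22 were lower.

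**Figure D2:**
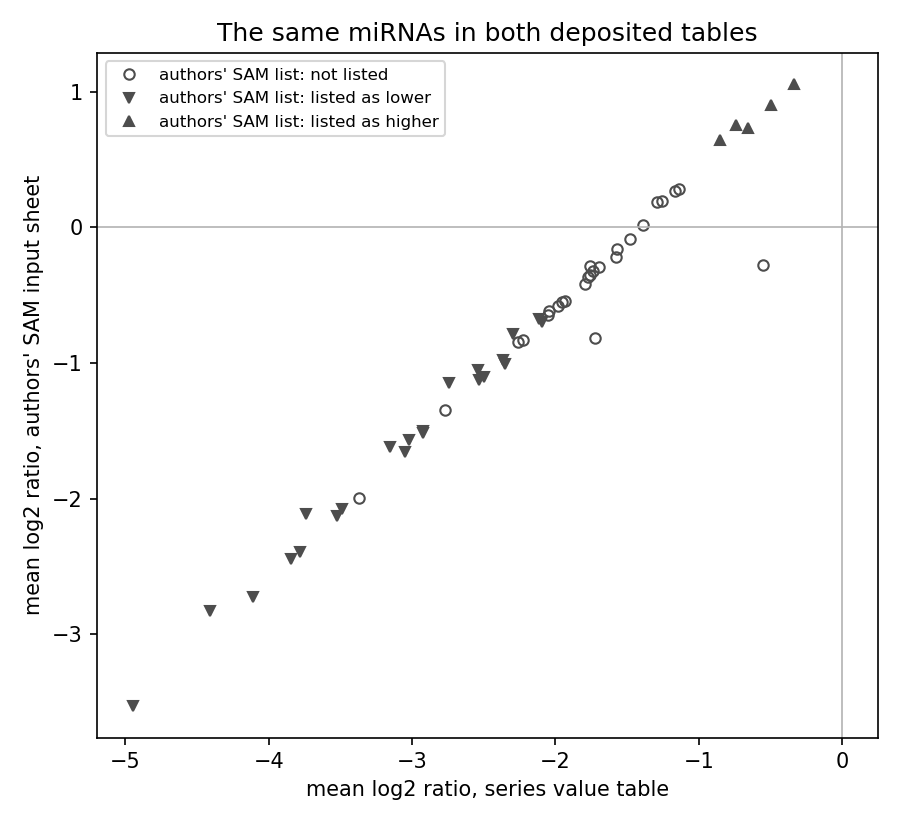
Mean log2 ratio of treated over untreated cells for the 52 miRNAs on both deposited tables, the series value table (horizontal axis) and the authors' SAM input sheet (vertical axis). Each point is a miRNA, and triangles mark the authors' SAM list; the 5 triangles pointing up lie above 0 on the SAM sheet and below 0 on the value table, as miR-320 does with 1.06 and -0.34.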

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

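Among the tests in this part, that of an imbalance between the dyes and those of brightness on each array were chosen only after the result was seen.

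The array-wide fall, with a mean of array medians of -2.25, is the pattern most open to a technical reading. A dye bias that changes with brightness was tested across the 59 miRNAs, which are not independent replicates, by relating mean log2 ratio to log2 Cy3 level. Spearman's rho was 0.084 (permutation p = 0.530, 95% bootstrap interval -0.18 to 0.35) and Pearson's r was 0.04 (permutation p = 0.734), in a family of these 2 relations. Per array, rho was -0.03, 0.08, -0.06 and 0.23 for replicates 1 to 4 (permutation p = 0.816, 0.550, 0.643 and 0.0892; adjusted over the 4 arrays 0.816, 0.816, 0.816 and 0.357), with slopes of -0.01, 0.03, -0.03 and 0.19 log2 per log2 unit of level. The bootstrap interval of rho for the mean ratios reaches past the limit of 0.3 set beforehand, so a trend stays open. Cy3 is also the denominator of the ratio. Where the levels share error with it, rho is pulled down and a rising trend could be hidden. An imbalance in labelling or scanning that moves every miRNA of an array alike, or a true fall of most miRNAs under LAQ-824, cannot be told apart on these arrays, which hold no dye swap and no RNA known to be unaffected. Turning the sign of other sets of arrays gave at most 1 call on the value table against 53 in the real orientation, 0 against 17 on the SAM sheet and 1 against 17 relative to the array median; the real orientation was the 1 of 8 with as many calls each time, and 8 are too few for a share under 0.05.

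MiR-92 had 1 array far from the others: replicate 4 was -1.63, and the other 3 arrays lay between -0.68 and -0.52. This was the 1 of 46 sets of 4 values with so large a gap, and chance alone marks about 1 set in 20. These values were not centred. The median of the tested miRNAs was -2.80 on replicate 4, against -1.78, -3.03 and -1.38 on replicates 1, 2 and 3. Gaps in centred values were not tested. A buffer spot, which holds no probe, had a log2 ratio of -1.52 on replicate 1, where the median of the tested miRNAs was -1.78. It was the 1 buffer spot with a ratio. Whether spots without a probe share the array-wide fall therefore cannot be told, and the spot leaves a technical part in that fall open.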

How the results depend on the processing

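The filter on spots that differ by over 1 log2 unit was chosen after seeing the data, as were all alternatives run on the SAM sheet, on the centred values and on pairs of cluster neighbours. On the value table the counts of 53 lower and 0 higher became 48 with a value on all 4 arrays, 55 with at least 2, 46 for miRNAs of the SAM sheet, 52 after scaling, 53 with robust eBayes, 52 with array weights, 57 with sign-flip SAM, 47 and 53 at adjusted p under 0.01 and 0.10, 45 without discordant spots, and 46 to 53 without 1 array, with 0 higher in each. Centring gave 17 calls, 8 higher and 9 lower; the SAM sheet gave 17 lower, its filled form 18 lower, the ordinary statistic 34 lower, and the authors' SAM list 27, 5 higher and 22 lower. Centring removed the array constant and also changed the moderation, from infinite to 3.64 prior degrees of freedom; the cause of the lost calls, and of the other differences, was not tested. On the SAM sheet the ordinary statistic gave 0 calls, sign-flip SAM 24, 3 of them higher, the authors' list 27, 5 of them higher, and leaving out 1 array 13 to 19, with 0 to 1 higher. Relative to the array median the ordinary statistic gave 3 calls, 1 higher and 2 lower, sign-flip SAM 23, and leaving out 1 array 8 to 16 calls, 2 to 5 of them higher and 6 to 11 lower; the fewest, 8, came without replicate 1. The mean array median was -0.80 on the SAM sheet and -2.54 to -1.99 without 1 array.

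For the lists, centring gave -0.86 for let-7, -0.14 for the miR-17 group, -0.45 for the miR-23, miR-27 and miR-24 clusters, -0.40 for miR-15 and miR-16, -0.53 for miR-29, 0.33 for miR-30 and 0.50 for the miR-125 group, none past 0.05. Camera's difference from other miRNAs, the same under both correlations, was -0.84, -0.024, -0.36, -0.29, -0.37, 0.52 and 0.59 in that order, none past 0.05. On the SAM sheet the miR-17 group (-0.97), miR-30 (-0.71) and the miR-125 group (-0.17) did not pass. Leaving out 1 array gave list means of -3.32 to -2.73, -2.71 to -2.14, -2.95 to -2.49, -3.13 to -2.13, -3.07 to -2.49, -2.27 to -1.58 and -2.29 to -1.45 in that order, with adjusted p from 0.0345 to 0.150; without replicate 4 no list passed. Scaling kept all 7 past the threshold.

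Of 209 values of named miRNAs under other settings, 151 kept direction and side, 31 lost and 1 gained the threshold, and 26 changed sign, 19 of them by centring and 7 on the SAM sheet. Centring moves all miRNAs of an array by one constant, so these sign changes say nothing about single miRNAs. Without 1 array, 164 of 172 kept both and 8 lost the threshold (miR-103 3 times, miR-181a 2 times, miR-99b, miR-107 and miR-130a). Centring turned the sign of miR-23b (0.13), miR-24 (0.29), miR-200c (1.75), miR-16 (0.019), miR-15b (0.49), miR-30a-5p (0.20), miR-30d (0.55), miR-99b (0.045), miR-125b (1.505), miR-125a (1.59), miR-181b (0.27), miR-181a (1.11), miR-34a (0.48), miR-107 (0.49), miR-103 (0.99), miR-130a (0.49), miR-128b (0.53), miR-320 (1.91) and miR-92 (1.40). The SAM sheet turned miR-200c (0.90), miR-125b (0.75), miR-125a (0.73), miR-181a (0.28), miR-103 (0.19), miR-320 (1.06) and miR-92 (0.64). Of 40 pairs of cluster neighbours, 19 differed by limma, 1 by the ordinary statistic and 15 to 19 without 1 array. No paired analysis was possible because there is 1 group, compared within each array. Signal over background per array was not used here.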

Other observations

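The comparison of neighbouring miRNAs, the tests on single spots and the test of the pairs' direction by brightness were chosen after the data were seen.

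MiRNAs whose genes lie together did not always change alike. A difference between miRNAs of 1 array is free of any constant shared by that array. Of 40 pairs of neighbours within 10000 bases, 19 differed (limma, adjusted p under 0.05), each with one sign on every array measured. The ordinary statistic called 1 of the 40 after adjustment, miR-17-5p over miR-19a by 2.94 ± 0.45 (SD, n = 4), and gave an unadjusted p under 0.05 for 15 of the 19, so most of these calls rest on the pooled spread. In the cluster on chromosome 13, miR-19a lay below miR-92 by a log2 difference of -3.26 ± 1.32, and miR-17-5p against miR-92 was -0.31 ± 1.26 and did not pass. MiR-141 minus miR-200c, both on chromosome 12, was -5.45 ± 1.15 (SD, n = 3), with the 2 spots of miR-141 over 1 log2 unit apart on 2 arrays. On chromosome 7, miR-182 lay above miR-96 by 2.09 ± 1.37 (SD, n = 4), with an unadjusted p of 0.0554 by the ordinary statistic. MiR-96 rests on 1 spot on 3 of the 4 arrays. On the other array its 2 spots lay over 1 log2 unit apart, so this difference is uncertain. Let-7a lay above let-7f by 2.02 ± 0.91 (SD, n = 4), though these differ little in sequence.

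Unequal change within clusters was set against technical explanations. The miRNA with the higher Cy3 level lay higher in 13 of the 19 pairs and lower in 6, so 31.6% went against most pairs. This is more than a false share of 5% allows (exact one-sided binomial p = 0.000241). That p takes pairs that share miRNAs as independent. It also supposes that at most 5% of limma's calls are false, though most rest on the pooled spread. The 6 pairs therefore argue only weakly against one rising or falling trend with brightness as the whole cause. Taking a straight line on log2 level off each array left 100% of the 19 pairs past the threshold but moved them by at most 0.20, below their median SD of 0.96, so it decides nothing and a part played by brightness stays open. Of 32 pairs with at least 3 arrays on both spots, the sign on the other spot was the same in 16 of the 16 that differed on one spot. It was the same in 18 of the 19 that differed on the other. The share was 97.1%, against 49.9% with the other spot shuffled over miRNAs (permutation p = 0.0003 and 0.001). The 2 spots of a miRNA correlated at 0.825 to 0.841 per array. A share above the shuffled one was therefore likely from the start, and these p-values add little. The repeated signs argue against disagreement between spots as the source of the direction in these pairs. Of the calls, 80% were also made on the other spot, short of the bound set for this test. Disagreement between spots thus stays open for the size of part of the differences and for pairs outside the 32, such as miR-141 and miR-200c. A different processing or decay of mature miRNAs, several of which come from more than 1 gene, may be a hypothesis, but it was not tested, and probe sequence, base content and cross-hybridisation stay open.

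Let-7g and miR-26b had a ratio on 2 arrays each and were not tested. Their log2 ratios were -5.06 and -3.12 for let-7g, and -6.14 and -5.56 for miR-26b. A further 6 miRNAs had a level on the authors' sheet and no ratio in the series value table: miR-342 at 826.7, miR-222 at 681, let-7i at 311, miR-148b at 266, miR-18 at 248 and miR-200b at 234 intensity units, as the authors' means. Of these, miR-200b had log2 ratios of -0.13 and 0.64 on 2 arrays of another sheet of the authors' workbook.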
